A study of Mus musculus with 18 samples.

How the data were processed

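RNA was measured by sequencing in mouse testis carrying either the wild-type Taf7l gene or a knock-in allele of it. Taf7l lies on the X chromosome and encodes a germ-cell relative of Taf7, a subunit of the general transcription factor TFIID. Per the labels, RNA was extracted with Trizol from frozen testes of C57BL/6 mice and made into libraries with a stranded total RNA kit. The labels name 18 samples, 3 of each genotype from whole testis, from pachytene spermatocytes and from round spermatids. Columns for the 6 whole-testis libraries were found in the tables used here, and the other 12 samples were not analysed here. No label says which libraries came from separate animals, so p-values measure the spread between these libraries, part of which may be technical.

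Per the file headers, 3 tables were deposited, for mRNA genes, noncoding transcripts and circular RNAs. Each holds whole-number counts per feature and library as the authors made them. The mRNA and noncoding tables also hold FPKM per library, and the circular RNA table holds RPM per library, that is, counts relative to all circular RNA counts of the library in the deposited table. The authors' deposited tables further give a mean per genotype (FPKM for the linear RNAs, a signal for the circles, with a small value in place of 0), a log2 ratio of those means, a p-value and an adjusted p-value. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the gene annotation, the use of strand in counting and the authors' test are not given in the sources used here. Noncoding transcripts of a gene can overlap each other and the coding gene, and near-identical gene copies share reads too. How shared reads were counted is not given, so values of both kinds are uncertain at the level of the single feature.

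The counts as deposited were tested between genotypes, 3 libraries against 3, with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Libraries were scaled by TMM, the p-values were two-sided and adjusted by Benjamini-Hochberg, and a feature was called changed at an adjusted p under 0.05. Fold changes compare the knock-in with the wild type. Genes and noncoding transcripts were kept by filterByExpr with its minimum count of 10 and minimum total of 15, and circles were kept when at least 3 of the 6 libraries were above 0. Levels are given as TMM-scaled CPM, counts relative to the library total. The standard error of a log2 fold change was derived from the quasi-likelihood F statistic. For named features that were called, where all libraries of one genotype were at 0, the fold was given as a lower bound against a floor of 3 counts over that group. Where a genotype held 1 to 3 counts, the ratio was given with a 95% exact counting interval. Such features that were not called are given as counts. Intervals and floors of this kind cover counting error only.

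The mRNA table held 22298 genes, 19784 of them above 0, and 15787 were tested. The noncoding table held 33433 transcripts and 9301 were tested, and the circular RNA table held 7391 circles and 3887 were tested. Depth ran from 17431309 to 21446420 counts per library in the mRNA table, from 1384224 to 1647421 in the noncoding table and from 14381 to 20127 counts in the circular RNA table. The common biological coefficient of variation was 11.1% for genes, 26.4% for noncoding transcripts and 43.4% for circles, so precision fell in that order. No library repeated another: between libraries of one genotype the chi-square per degree of freedom of the gene counts lay between 5.54 and 10.8.

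Before the data were examined, 20 gene lists were fixed: TFIID subunits and germ-cell relatives of the basal factors, spermatogonia, meiotic prophase, round spermatid and acrosome, elongating spermatid and chromatin compaction, flagellum and axoneme, piRNA pathway and germ granules, sperm energy metabolism, sex-linked genes expressed in spermatids, cell death, Sertoli cells, Leydig cells, peritubular myoid and smooth muscle, macrophages and leukocytes, endothelium and connective tissue, erythrocytes, epididymis, adipose tissue, stress and immediate early response, and mitochondrial genome. Lists with at least 5 measured members were tested with camera (limma) at its preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. KEGG pathways and GO components of 10 to 500 tested genes, as annotated in the deposited mRNA table, were tested with camera, with the preset and an estimated correlation, and were added after the data were seen.

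The genes named in the text also followed a rule fixed before the data were examined. Taf7l was given in every library. All measured members of the TFIID list were counted. In the mRNA table, the 10 genes with the largest fitted rise and the 10 with the largest fitted fall among those called were named, passing over symbols of the Gm or Rik form unless fewer than 5 other genes passed in that direction. For noncoding and circular RNA, 5 features per direction were named, with no symbol passed over. Where fewer passed, they were followed by those of the lowest p-value whose libraries did not overlap between genotypes, as values without a claim of change. In each list, up to 4 called members were named, by the smallest adjusted p, and otherwise the 2 members of the highest level in the wild type. Positions of genes come from a RefSeq gene table of the GRCm38 assembly, which is the assembly behind mm10. A row was found by symbol or synonym for 15610 of the tested genes.

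The transcript length of a gene was taken from the ratio of its counts to its FPKM, which gave a value for 100% of the tested genes. A length-corrected fit, added after the data were seen, removed a smooth trend (loess, span 0.3) of each library on the logarithm of that length through offsets in the edgeR model. The alternatives fixed before the data were examined were no filter on low counts, a 5 times higher minimum count, DESeq2 size factors, quantile normalization, the DESeq2 Wald test (DESeq2 1.42.0), limma voom, 2 other thresholds, the replicate number as a block, sums per gene for noncoding transcripts, and each library left out in turn. Added after the data were seen were the length correction, limma on log2(FPKM + 1) for genes at 1 or more in at least 3 libraries, library sizes of the mRNA table for the other tables, and filterByExpr for circles.

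The tests were run on simulated data with known answers. Of 67 genes changed 1.3-fold among 15787, 17.9% were recovered, and 43.3% of 67 genes changed 1.5-fold. Of 66 genes changed 2-fold, 74.2% were recovered. For noncoding transcripts 25.4% were recovered at a 2-fold and 65.2% at a 4-fold change, among 9301. For circles 1.49% were recovered at a 2-fold, 15.4% at a 4-fold and 30.8% at an 8-fold change, among 3867 with any simulated count. In these same simulations 11.8% of 102 gene calls, 10% of 70 noncoding calls and 0 of 31 circle calls were false. Over 10 simulations of each table drawn with a spread that follows the mean level, 4.35% of the calls were false for genes, 5.23% for noncoding transcripts and 0.621% for circles. With a spread that also differs between genes of the same level, 10% of the gene calls were false.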

Results

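The data cover coding, noncoding and circular RNA of whole testis from 3 wild-type and 3 Taf7l knock-in libraries of C57BL/6 mice. The comparison asks how the testis transcriptome differs between mice with the knock-in allele and wild-type mice. Wild-type libraries held 18770025, 18547759 and 17431309 counts of mRNA genes. Knock-in libraries held 18602187, 18893765 and 21446420. Between 18262 and 18427 genes were detected per library. Samples of pachytene spermatocytes and round spermatids were not analysed here.

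Taf7l itself (ENSMUSG00000009596, mm10 chromosome X from 134460116 to 134476505) was counted 507, 551 and 531 times in the wild-type libraries. It was counted 472, 525 and 581 times in the knock-in libraries. The level was 29.0 ± 1.25 CPM, TMM-scaled counts relative to the library total, in the wild type and 26.8 ± 0.745 in the knock-in (mean ± SD, n = 3 each). The log2 fold change was -0.11 with a 95% interval from -0.29 to 0.07, and it did not pass the test (edgeR, adjusted p = 0.632). A knock-in allele need not alter the amount of its own transcript, and counts per gene do not show the edited codon, so this value does not check the labels. None of the 25 measured TFIID subunits and relatives was called changed, nor was any adjusted over the list alone. Taf9, a core TFIID subunit, had a log2 fold change of -0.09 ± 0.08 (SE) and Gtf2a1l, the germ-cell relative of the large TFIIA subunit, of -0.04 ± 0.06. Across the list the values ran from -0.19 to 0.23 with a median of -0.01 (camera, adjusted p = 0.703).

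Of 15787 mRNA genes tested, 155 differed between the genotypes, 139 higher and 16 lower in the knock-in. The changes were mostly small: 14 of the genes that rose and 5 of those that fell reached 2-fold. The median rise was 41.0% and the median change of those that fell was -41.8%. Apart from H2ac19 and the Y-linked copies described further on, the largest fitted rise was that of Sgcb, which encodes beta-sarcoglycan of the dystrophin-associated membrane complex (ENSMUSG00000029156, chromosome 5 from 73632749 to 73647737). Its level was 5.91 ± 0.604 CPM in the wild type and 20.7 ± 0.419 in the knock-in (SD, n = 3 each), a log2 fold change of 1.80 ± 0.12 (SE; edgeR, adjusted p = 0.000272). Ybx1, a cold-shock-domain protein that binds DNA and RNA (ENSMUSG00000028639, chromosome 4 from 119277327 to 119296265), rose from 73.0 ± 6.02 to 154 ± 15.2 CPM, a log2 change of 1.07 ± 0.09. Cdk11b, a kinase that acts in transcription and splicing (ENSMUSG00000029062, chromosome 4 from 155624841 to 155649935), rose from 16.5 ± 1.53 to 36.7 ± 2.89 CPM, a log2 change of 1.15 ± 0.10. Further genes with the largest rises were the spliceosome-associated Wbp11 (log2 1.37 ± 0.18), Cby1 of the ciliary base (1.16 ± 0.23), the spindle-associated Ckap2 (1.01 ± 0.12), the ribosomal protein gene Rpl28 (0.84 ± 0.10) and Ccdc124 (0.81 ± 0.11). Sap18b also rose (1.28 ± 0.20). It is a close copy of Sap18, whose log2 fold change was 0.01 ± 0.08, so its value is uncertain.

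H2ac19, a replication-dependent histone H2A gene (ENSMUSG00000063954, chromosome 3 from 96239779 to 96240374), was at 0 in each wild-type library and at 628, 393 and 647 counts in the knock-in libraries, at least 519-fold higher. Its near-identical neighbour H2ac18 had 34300 counts in the wild type and 35154 in the knock-in. How reads shared by the pair were counted is not given, so the single-gene value is uncertain. The Y-linked Gm20905, Gm20894 and Gm20835, which the naming rule passes over, had identical counts in every library and each rose by 2.86 on the log2 scale. They stand for 1 measured value.

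The largest fitted fall was that of 1300017J02Rik (log2 -3.36), which the naming rule passes over. It was followed by Btbd35f9, a member of an X-linked multi-copy family of BTB-domain genes, with 157 counts in the wild type and 22 in the knock-in (log2 -2.90 ± 0.48 SE; edgeR, adjusted p = 0.0268). As a family member with close copies its value is uncertain. Pfkm, the muscle form of the glycolytic phosphofructokinase (ENSMUSG00000033065, chromosome 15 from 98092589 to 98132447), fell from 37.6 ± 4.42 to 17.9 ± 5.74 CPM (log2 -1.07 ± 0.20). The glucose transporter gene Slc2a3 (ENSMUSG00000003153, chromosome 6 from 122727809 to 122802363) fell from 208 ± 5.89 to 120 ± 24.3 (log2 -0.79 ± 0.12). Tcp1, a subunit of the cytosolic chaperonin, was the most abundant of the 10 named genes that fell, from 781 ± 24.3 to 527 ± 75.1 CPM (log2 -0.57 ± 0.09). The others were the sialyltransferase gene St3gal2 (-1.65 ± 0.28), the zinc-finger helicase gene Znfx1 (-0.84 ± 0.15), the ribosomal protein gene Rpl5 (-0.78 ± 0.12), Angel1 (-0.74 ± 0.11), the potassium-chloride cotransporter gene Slc12a7 (-0.72 ± 0.14) and Smok3b of the multi-copy sperm motility kinases (-0.78 ± 0.15).

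**Figure D1:**
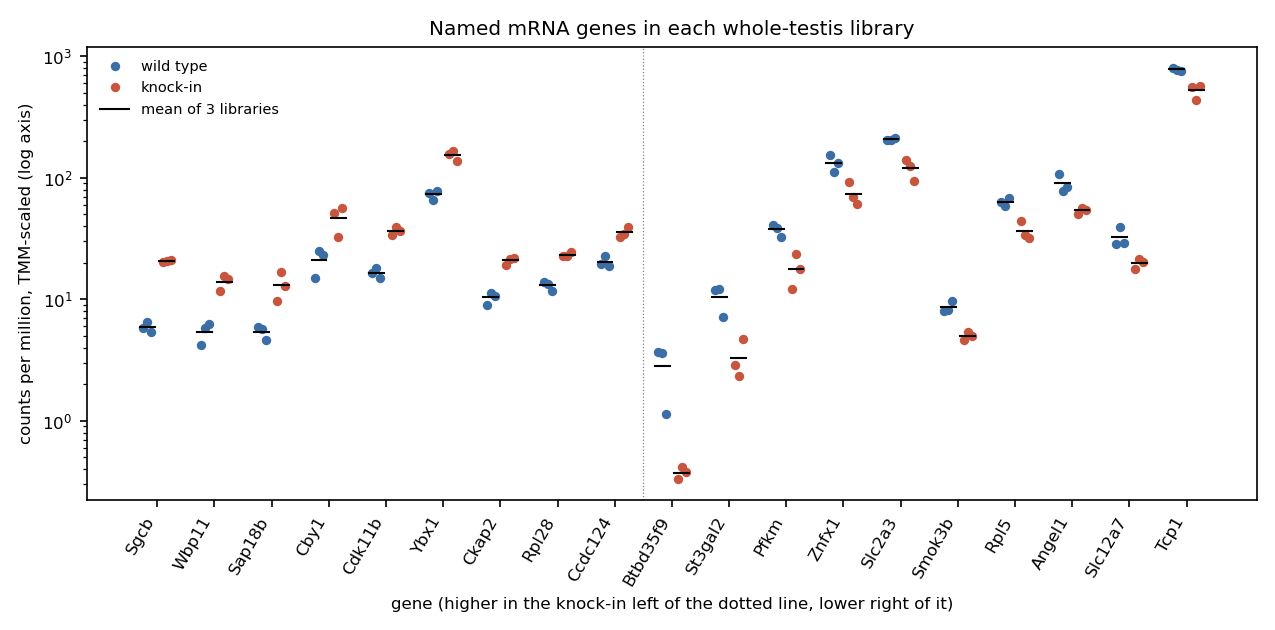
CPM after TMM scaling (y axis, log scale) of the named mRNA genes other than H2ac19 (x axis) in 3 wild-type (blue) and 3 knock-in (red) whole-testis libraries; each point is a library and each bar the mean of 3. The libraries of the genotypes do not overlap for any gene shown, as for Sgcb with means of 5.91 and 20.7.

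Of the called genes, 3 lay on the X chromosome (Btbd35f9 and, chosen after their values were seen, Gm6760 and 1700020N15Rik), 2.01% of the 149 called genes with a position, against 4.35% of tested genes (Fisher's exact test, two-sided, p = 0.222). Of 61 tested genes within 5 Mb of Taf7l, 0 were called. The libraries of the genotypes did not overlap for 2925 tested genes, 18.5%, where chance gives 10% on average over groupings of the libraries. Since genes vary together, a single grouping can lie far from that average, and the share in other groupings was not computed. The authors' deposited table lists 446 genes at an adjusted p under 0.05, 361 higher and 85 lower, among them 147 of the 155 called here. The number of calls was 74, 32 and 20 without wild-type library 1, 2 or 3, and 108, 125 and 11 without knock-in library 1, 2 or 3. Of the 34 named genes that were called, H2ac19, Sgcb, Cdk11b and Ybx1 were called in each of these 6 fits. Slc12a7 and Smok3b were called in none of them. The DESeq2 test gave 456, quantile normalization 273 and limma on FPKM 355.

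Genes called higher had a median implied length of 1207 bp against 3009 bp for tested genes. The shortest 10% of genes, with a median log2 fold change of 0.11, held 74 of the 139 genes called higher. In these genes the median deviation from the mean of the 6 libraries was -0.01, -0.06 and -0.08 in the wild-type and 0.07, 0.03 and 0.08 in the knock-in libraries. The longest 10% of genes had a median log2 fold change of -0.03, and there the libraries of the genotypes overlapped, with deviations of -0.01, 0.02 and 0.04 in the wild-type and -0.03, 0.05 and -0.05 in the knock-in libraries. With this length trend removed 82 genes were called, 66 higher and 16 lower, of which 75 were also called without the correction.

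**Figure D2:**
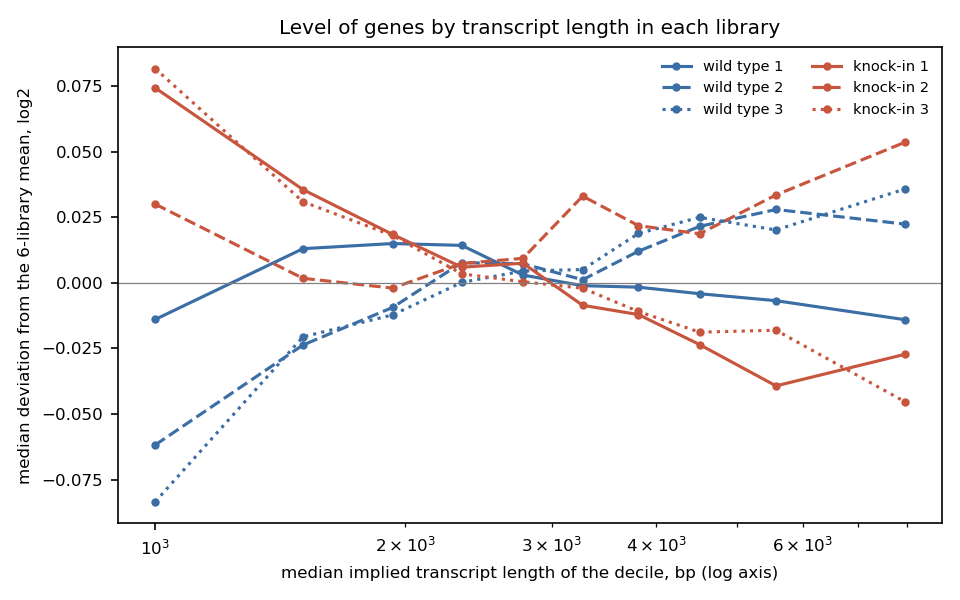
Median deviation of genes from their mean over the 6 libraries on the log2 scale (y axis) for deciles of the tested genes by implied transcript length in bp (x axis, log scale), one line per library, wild type in blue and knock-in in red. In the shortest decile the knock-in libraries lie between 0.03 and 0.08 and the wild-type libraries between -0.08 and -0.01.

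The mitochondrial genome list had the largest median fold change of the tested lists. All 13 of its protein-coding transcripts had a log2 fold change above 0, with a median of 0.41, and 6 were called higher, 10 adjusted over the list alone. mt-Atp6, a subunit of ATP synthase, rose from 114 to 174 CPM (log2 0.60 ± 0.07 SE; edgeR, adjusted p = 0.00814). mt-Co2, a subunit of cytochrome oxidase, rose from 246 to 346 (0.49 ± 0.07), mt-Cytb of complex III from 178 to 257 (0.53 ± 0.07) and mt-Nd3 of complex I from 14.3 to 23.4 (0.71 ± 0.09). The list passed camera with the preset correlation (adjusted p = 7.66e-24) but not with an estimated correlation (adjusted p = 0.274 with an estimated correlation) or by fry (adjusted p = 0.0621). Mitochondrial transcripts took 0.589% ± 0.0423 of the counts in the wild type and 0.720% ± 0.0507 in the knock-in (SD, n = 3 each), and the libraries did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). After the length correction the median was 0.35 and 2 members were called, mt-Atp6 and mt-Cytb.

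Among genes of late sperm formation, 4 of 32 measured members of the elongating spermatid and chromatin compaction list were called, all higher, and 9 adjusted over the list alone. They were Prm2, a protamine of the kind that replaces histones in sperm, from 1556 ± 149 to 2243 ± 216 CPM (SD, n = 3 each; log2 0.53 ± 0.09 SE), the sperm histone gene H2bl1 (0.69 ± 0.12), Smcp of the sperm mitochondrial sheath (0.40 ± 0.07) and Odf3 of the flagellar outer dense fibres (0.36 ± 0.06). The other protamine gene, Prm1, had a log2 fold change of -0.31 ± 0.12 and did not pass (edgeR, adjusted p = 0.303). The list median was 0.10 (camera, adjusted p = 3.20e-05; adjusted p = 0.94 with an estimated correlation). Of the 32 members, 21 had a log2 fold change above 0 and 11 below. Among the 10 most abundant members 6 lay above 0, with a median of 0.02. The calls of Prm2, H2bl1 and Odf3 were each kept in 2 of the 6 fits without 1 library, and that of Smcp in 1. Members of the list are short, with a median implied length of 1345 bp. With the length trend removed the median was 0.01 and the list did not pass (camera, adjusted p = 0.156). The log2 fold changes were then 0.38 for Prm2, 0.49 for H2bl1, 0.31 for Smcp and 0.31 for Odf3, and none of them was called (adjusted p from 0.0565 to 0.0930).

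Of the flagellum and axoneme list 3 of 42 measured members were called, all higher, and 6 adjusted over the list alone: Meig1, needed for assembly of the sperm tail (log2 0.59 ± 0.08 SE), Rsph1 of the radial spokes (0.36 ± 0.07) and Cfap69 (0.35 ± 0.06). The list median was 0.06 (camera, adjusted p = 0.00462; adjusted p = 0.94 with an estimated correlation), and the call was lost without wild-type library 2 (adjusted p = 0.308), knock-in library 1 (0.337) or knock-in library 3 (0.0806). Of the 42 members, 27 had a log2 fold change above 0 and 15 below. With the length trend removed the list passed with a median of 0.06 (camera, adjusted p = 0.0102), and Meig1 was still called. Rsph1 (log2 0.32, adjusted p = 0.0840) and Cfap69 (log2 0.29, adjusted p = 0.0906) kept most of their fold change and were not. In the round spermatid and acrosome list 2 of 32 were called, the acrosomal membrane gene Spaca4 (0.39 ± 0.06) and the acrosomal Tmem190 (0.59 ± 0.09), and the list did not pass (median 0.04, camera, adjusted p = 0.0961), with 5 members past the threshold adjusted over the list alone, the others being Spaca7, Acrbp and Acr. The list did pass without wild-type library 1 (adjusted p = 0.0194), wild-type library 3 (0.0152) or knock-in library 2 (0.00583). With the length trend removed its median was -0.02, and neither Spaca4 (log2 0.26, adjusted p = 0.145) nor Tmem190 (log2 0.43, adjusted p = 0.0670) was called. In the sperm energy metabolism list 1 of 20 was called, Slc2a3, which fell, and 3 passed adjusted over the list alone, with Glul and Pgam2 higher (list median 0.02, mean -0.03, camera direction down, adjusted p = 0.703).

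Earlier germ cell lists held no called gene. Over all genes 155 of 15787 were called, so lists of this size would hold few calls in any case. Spermatogonial genes had a median log2 fold change of 0.07 over 18 members (Kit -0.00 ± 0.14 SE, Dmrtb1 0.17 ± 0.07), meiotic prophase genes -0.07 over 33 (Ldhc -0.14 ± 0.07, Hspa2 0.14 ± 0.06) and piRNA pathway genes -0.03 over 24 (Tdrd6 -0.10 ± 0.07, Mael -0.03 ± 0.06), each with an adjusted p = 0.703 by camera. Among meiotic genes 1 passed adjusted over the list alone, Syce3, and 24 of the 33 had a log2 fold change below 0. Sex-linked genes expressed in spermatids had a median of 0.01 over 30 members (Akap4 -0.14 ± 0.08, Tsga8 0.07 ± 0.06; adjusted p = 0.818) and cell death genes -0.03 over 33 (Diablo -0.13 ± 0.06, Birc2 -0.16 ± 0.06; adjusted p = 0.602).

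Markers of somatic cells held 1 called gene, Pnpla2, the lipase of fat stores, in the adipose list of 12 (log2 0.46 ± 0.06 SE; list median 0.08, camera, adjusted p = 0.424), and 1 passed adjusted over the list alone, again Pnpla2. All 11 peritubular myoid and smooth muscle genes had a log2 fold change above 0, with a median of 0.25. None was called over all genes and 5 passed adjusted over the list alone, namely Myl9, Myh11, Smtn, Des and Tpm2. Acta2, smooth muscle actin, had 0.17 ± 0.07 and Actg2 0.04 ± 0.06. The list passed camera (adjusted p = 0.000169) but not with an estimated correlation (adjusted p = 0.94 with an estimated correlation). Sertoli cell genes had a median of 0.02 over 28 members (Clu 0.12 ± 0.10, Tuba3b 0.02 ± 0.06; adjusted p = 0.818), and Leydig cell genes 0.08 over 19 (Cyp17a1 0.23 ± 0.10, Insl3 0.03 ± 0.09; adjusted p = 0.383), 1 of them, Cyp11a1, past the threshold adjusted over the list alone. The Leydig list passed without wild-type library 2 (adjusted p = 0.0102). Medians were 0.06 for 14 macrophage and leukocyte genes (Lyz2 -0.14 ± 0.16, Mrc1 -0.11 ± 0.07; adjusted p = 0.818), 0.06 for 17 endothelial and connective tissue genes (Col3a1 0.15 ± 0.15, Sparc 0.02 ± 0.08; adjusted p = 0.590) and 0.37 for 5 erythrocyte genes (Hbb-bs 0.16 ± 0.26, Alas2 -0.16 ± 0.08; adjusted p = 0.602). Stress and immediate early genes had a median of 0.03 over 15 members (Dnajb1 0.01 ± 0.06, Ddit3 0.18 ± 0.10; adjusted p = 0.590). The epididymis list had 4 measured members, Rnase10 at -0.51 ± 0.15 and Cuzd1 at -0.32 ± 0.54 among them, and was not tested. Rnase10 and Wfdc10 were the 2 members that passed adjusted over the list alone. Members that passed only adjusted over a list alone are named here and in the other lists after their values were seen. Of the 19 tested lists, 4 passed with the preset correlation, all upward, and 0 with an estimated correlation. The latter test has little power with so few libraries. The preset of 0.01 in turn leaves out joint variation, estimated at 0.394 to 0.568 for these 4 lists. With it, at least 4 lists passed in 9 of the 10 groupings of the libraries, the real one included.

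**Figure D3:**
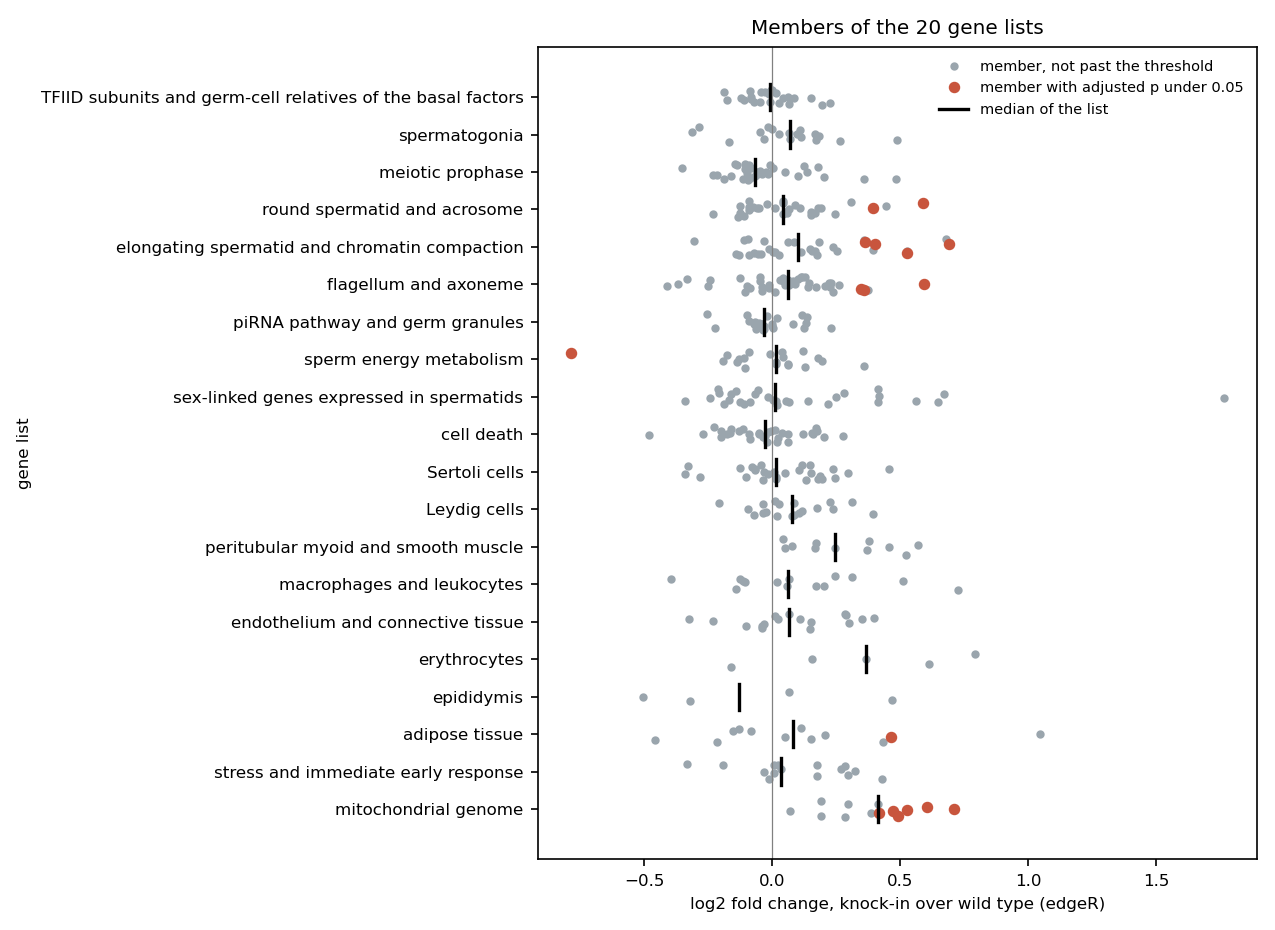
Log2 fold change of the knock-in over the wild type (x axis) for the measured members of the 20 gene lists (y axis); grey points are members that were not called, red points members with an adjusted p under 0.05, and black bars list medians. All 13 mitochondrial points and all 11 peritubular myoid points lie above 0, with medians of 0.41 and 0.25.

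Of 9301 noncoding transcripts tested, 9 were called, 5 higher and 4 lower, each carrying the symbol of a gene in its annotation. The libraries of the genotypes did not overlap for 1484 transcripts, 16%, where chance gives 10% on average over groupings of the libraries, the share in other groupings not being computed. A transcript of Chd5, a chromatin remodeller (ENSMUST00000124423), had 1111, 899 and 917 counts in the wild type and 0 in each knock-in library, at least 1036-fold lower (edgeR, adjusted p = 6.85e-05). The coding gene Chd5 had a log2 fold change of 0.11 ± 0.07 (SE) in the mRNA table. A transcript of Gtf2a1l (ENSMUST00000234392) fell from 1417 ± 125 to 599 ± 57.8 CPM (SD, n = 3 each; log2 -1.24 ± 0.10), with -0.04 ± 0.06 for the coding gene. Transcripts of Hnrnpu, an RNA-binding nuclear scaffold protein (log2 -2.94 ± 0.26), and of Atp5b, a subunit of ATP synthase (-1.19 ± 0.10), also fell, while the coding Hnrnpu gene rose (0.39 ± 0.06, adjusted p = 0.0254).

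Called transcripts at 0 in each wild-type library were those of Pabpc1, the cytoplasmic poly(A)-binding protein, with 391, 763 and 600 counts in the knock-in (at least 551-fold higher), AW554918 with 163, 122 and 124 (at least 128-fold) and Wdr48 with 40, 31 and 55 (at least 39.6-fold). The coding Pabpc1 gene rose too (0.44 ± 0.07 SE; edgeR, adjusted p = 0.0268). A transcript of the orphan receptor gene Nr6a1 had 3 counts in the wild type and 220 in the knock-in, a ratio of 69.1 with a 95% exact counting interval from 23.3 to 337. All 3 wild-type counts came from wild-type library 2. A transcript of the centrosomal gene Cep41 rose by 1.28 ± 0.14 on the log2 scale. The Nr6a1 call was lost in each of the 6 fits without 1 library (adjusted p from 0.0707 to 0.180). Its fitted log2 fold change ran from 5.41 without wild-type library 1 to 9.17 without wild-type library 2, where the wild type was at 0 and the fitted value is no bound. The Wdr48 call was lost in 5 of the 6, all but that without wild-type library 2, and the Cep41 call in 4, all but those without wild-type library 2 or knock-in library 1. Limma voom did not call the transcripts of Pabpc1, AW554918, Wdr48, Nr6a1 and Chd5. With the replicate number as a block, 7 of the 9 noncoding calls were lost. A Cyc1 transcript had 86 counts in the wild type and 1 in the knock-in and did not pass (adjusted p = 0.0696), though it did by the DESeq2 test, with quantile normalization and without a filter. Because overlapping transcripts can share reads, these values are uncertain at the level of the transcript. The count of calls was 129 without a filter on low counts, 110 by the DESeq2 test, 20 with sums per gene, and 15 both with a higher minimum count and without knock-in library 3. The authors' deposited table lists 114 at an adjusted p under 0.05.

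**Figure D4:**
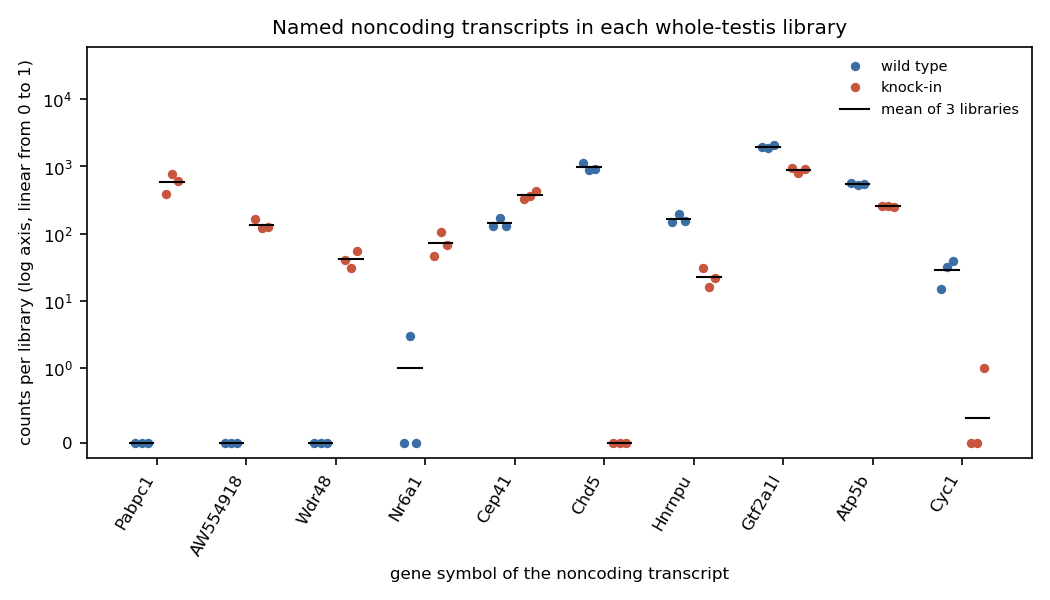
Counts per library (y axis, log scale above 1 and linear from 0 to 1) of the 10 named noncoding transcripts, by gene symbol (x axis), in 3 wild-type (blue) and 3 knock-in (red) libraries; each point is a library and each bar the mean of 3. The Chd5 transcript lies between 899 and 1111 counts in the wild type and at 0 in the knock-in, and the Pabpc1 transcript at 0 in the wild type and between 391 and 763 in the knock-in.

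Of the 7391 circular RNAs, which are detected by reads across a back-spliced junction, 78.5% were annotated to exons and 1086 were found in all 6 libraries. The hosts with the most circle counts over both genotypes were Bbs9, a ciliary transport gene (2026 counts over 12 circles), Ep400 (1942), Tulp4 (1480) and Strbp (1399). Ep400 led Bbs9 in the wild type (935 against 835 counts), and Bbs9 led in the knock-in (1191 against 1007). Relative to mRNA counts, circles took 841 ± 74.4 CPM in the wild type and 891 ± 40.9 in the knock-in (SD, n = 3 each; exact permutation test, two-sided, p = 0.4). None of 3887 tested circles was called by edgeR, with 191 (4.91%) at an unadjusted p under 0.05. The DESeq2 test called 0, limma voom 2 and the edgeR fit with quantile normalization 1, and the authors' deposited table lists 0. At a median of 5 counts over the 6 libraries, changes of most circles were not detectable at this depth.

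The highest-ranked circle lay antisense to Ppp2r3d on mm10 chromosome 9 from 124423792 to 124440885, with 20 counts in the wild type and 73 in the knock-in (edgeR, adjusted p = 0.143; 0.00629 without knock-in library 2). An exonic Bbs9 circle (chromosome 9 from 22643745 to 22679064) had 390 and 626 counts, a log2 fold change of 0.52 ± 0.16 (SE; edgeR, adjusted p = 0.979), and was among the 2 circles called by limma voom and was the circle called with quantile normalization. The other circle called by limma voom, on chromosome 1 from 97182978 to 97189368 with no host gene, is named after its value was seen. Without a claim of change, and in counts of the wild type and the knock-in, the remaining named circles that were higher in the knock-in were from Tbc1d5 (13 and 48; chromosome 17 from 50917527 to 50920603), Acot7 (3 and 25; chromosome 4 from 152206764 to 152237766) and Lamp2 (0 and 14; chromosome X from 38430918 to 38442140). Those that were lower were from Qrich1 (37 and 11; chromosome 9 from 108528589 to 108544977), Catsperb (88 and 53; chromosome 12 from 101415229 to 101463185), Efcab11 (23 and 5; chromosome 12 from 99854610 to 99855639), Ap3b1 (15 and 1; chromosome 13 from 94528165 to 94547893) and Deup1 (10 and 0; chromosome 9 from 15575148 to 15612156). Each of these had an adjusted p = 0.979.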

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

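Chosen only after the data were seen were the length correction, limma on FPKM, other library sizes or filterByExpr for noncoding and circular RNA, and all pathway tests. No value changed sign while past the threshold in any fit, and Taf7l stayed below the threshold with log2 fold changes from -0.15 to -0.08. Calls in the mRNA table numbered 155, against 19 with a 2-fold minimum, 84 at an unadjusted p under 0.05 with 2-fold, 273 with quantile normalization, 456 by DESeq2, 355 by limma on FPKM and 82 with the length correction, and from 11 to 125 with 1 library left out. Of the 155, 68 were called under 8 other fits of the 6 libraries (all but limma on FPKM), and 8 also in each fit without 1 library: H2ac19, Sgcb, Cdk11b, Ybx1, Fam50b, Cfap45, Rpl37 and Gm11808, the last 4 chosen after their values were seen. Fewer libraries alone lower the count, and beyond that the cause was not tested. Noncoding calls numbered 9, against 240 at an unadjusted p with 2-fold, 129 without a filter, 15 with a 5 times higher minimum, 110 by DESeq2 and 20 summed per gene, and from 6 to 15 with 1 library left out. Limma voom called 6, and 5 of the 9 lost their call by it. Circle calls numbered 0, against 170 at an unadjusted p with 2-fold, 1 with quantile normalization, 2 by voom, and from 0 to 1 with 1 library left out; the cause was not tested. Of the 34 named mRNA genes that were called, 29 lost the call without knock-in library 3, 25, 21 and 16 without wild-type library 3, 2 or 1, 11 and 5 without knock-in library 1 or 2, and 14 with the length correction, where some folds hardly moved (Cby1 1.11, Znfx1 -0.82, Smok3b -0.79 and Slc12a7 -0.70, adjusted p from 0.0501 to 0.0743), and Ldhc gained it with quantile normalization.

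Lists past the threshold numbered 4, against 0 with an estimated correlation, where values of 0.394 to 0.568 stood in place of the preset 0.01, and 0 by fry, which does not compare a list with other genes. With so few libraries camera has little power at an estimated correlation. Its smallest unadjusted p was 0.0144 among lists and 0.0209 among KEGG pathways. For cardiac muscle contraction, estimated at 0.007 and so below the preset, the unadjusted p by camera still went from 0.0013 to 0.0269. A lost call by itself therefore says little against a list. Where the estimated correlation was high, the unadjusted p by camera went further. It went from 0.000973 to 0.462 for the flagellum list, from 3.36e-06 to 0.284 for the elongating list and from 2.66e-05 to 0.118 for the myoid list. The value of 0.0144 was that of the mitochondrial list. Genes of these lists varied together, which the preset leaves out, so their lost calls cannot be put down to low power alone. Adjusted p with an estimated correlation and by fry were 0.94 and 0.80 for the elongating spermatid list, 0.94 and 0.80 for the flagellum list, 0.274 and 0.0621 for the mitochondrial list and 0.94 and 0.21 for the myoid list. The elongating list had 0.156 with the length correction; the flagellum list had 0.0812 by limma on FPKM and from 2.32e-09 to 0.337 with 1 library left out. KEGG pathways past the threshold numbered 7, against 0 with an estimated correlation, 0 by fry and 0 with the length correction. There the spliceosome and lupus pathways still had medians of 0.047 and 0.117. Over all alternatives the adjusted p ran from 7.81e-11 to 0.94 for the elongating list, from 1.68e-05 to 0.94 for the myoid list and from 9.93e-29 to 0.274 for the mitochondrial list. The round spermatid and acrosome list passed with quantile normalization (0.0426).

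With the replicate number as a block, 178 genes, 2 noncoding transcripts and 0 circles were called, with 4 lists and 7 pathways. By that fit 7 of the 9 noncoding calls and 4 of the 34 calls of named mRNA genes were lost. Correlations of same-numbered libraries of the mRNA table were 0.14, 0.08 and 0.03, and 2 of 3 wild-type libraries correlated best with their own number, and the numbers were not taken as pairs. A pseudocount and transcript-level mRNA tests were not run, since the tables hold counts per gene, nor was any test of sorted cells. Circle depth limits what could be called, as 1.49% of simulated 2-fold changes were recovered.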

Other observations

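All tests of explanations below, other than the regrouping of libraries, were chosen after the results were seen, as were the pathway tests. Of 329 KEGG pathways 7 passed camera with the preset correlation, all upward, and 0 with an estimated correlation. The ribosome pathway held 132 tested genes, 21 called higher and 1 lower, with a median log2 fold change of 0.13. Oxidative phosphorylation had 9 of 125 genes called higher (median 0.08), the spliceosome pathway 4 of 133 (0.06), and the lupus pathway, whose genes are largely histones, 3 of 110 (0.21). The other 3 pathways past the threshold, Parkinson disease, thermogenesis and alcoholism, had medians of 0.07, 0.04 and 0.08. Of 490 GO components 24 passed, 23 upward, among them the SWI/SNF chromatin remodelling complex with 2 of 18 genes called (median 0.14), and the SCF ubiquitin ligase complex passed downward with a median of -0.07 over 60 genes. None of these components passed with an estimated correlation.

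Regrouping the 6 libraries gives 10 splits, too few for a share under 0.05. By genotype 155 mRNA genes were called, and 1 split, the real one, reached that; the highest other split gave 2. For noncoding transcripts the counts were 9 by genotype and 1 in the highest other split, again reached by 1 split. For circles, 0 were called by genotype and 1 in the highest other split, so all 10 splits gave as many. List calls behaved otherwise: 9 of the 10 splits had at least the 4 lists found by genotype, the highest other split having 15, and 5 of the 10 splits had at least 7 pathways, the highest other having 45. Lists that pass with the preset correlation in regrouped libraries point to genes of a list that vary together between samples. The other splits mix the genotypes unevenly, so part of any genotype difference stays in them. Passes in these splits can therefore hold a part of the genotype contrast itself. Set beside these splits, the size of the mitochondrial shift was larger by genotype, with a median of 0.41 against at most 0.20 in any other split, although the list passed camera in 6 of the 10 splits. For the elongating spermatid list the real median of 0.10 was below the 0.15 of the highest other split, for the flagellum list 0.06 against 0.13, and for the myoid list 0.25 against 0.24. In the other splits from 8 to 13 mitochondrial and from 6 to 11 myoid members shared a sign, so full agreement was not particular to genotype.

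The upward pathways may in part follow the trend by transcript length. With a trend fitted on genes outside the pathways removed, 3 of the 7 stayed past the threshold by camera, namely ribosome (adjusted p = 0.0252), spliceosome (0.0485) and lupus (0.0110). With the trend fitted on all genes none did, but the folds moved unequally. The median went from 0.062 to 0.047 for spliceosome (camera, adjusted p = 0.0601), from 0.208 to 0.117 for lupus (0.0557) and from 0.133 to 0.018 for ribosome (0.178). Against 10000 random lists matched on length and level, the medians stood at percentile 100 for lupus, 99.97 for ribosome, 99.93 for spliceosome, 99.59 for alcoholism, 94.2 for Parkinson disease, 90.8 for thermogenesis and 89.6 for oxidative phosphorylation. Genes of the random lists were drawn one by one. Their ranges therefore leave out joint variation and are too narrow for lists whose genes vary together. For spliceosome and lupus, medians of 0.047 and 0.117 stayed with the trend removed. They lay above matched ranges of uncorrected values, from -0.024 to 0.039 and from 0.013 to 0.104. Because these ranges leave out the joint variation of the genes (estimated correlation 0.020 and 0.076), they cannot decide whether length was the whole cause. For none of the 7 pathways can the trend and a change of its genes be told apart. Whether ribosome, spliceosome and lupus passed camera depended on which genes set the trend. The genes left out were those of pathways picked for their rise. Leaving them out can weaken the fitted trend and so favour their calls. The ribosome median was 0.035 by that fit, against 0.018 with the trend fitted on all genes. For the mitochondrial list the tables argue against length as the whole cause, since the median was 0.41 before and 0.35 with the trend removed. Both lay above the range from -0.05 to 0.18 of matched lists, which leaves out the joint variation of these genes (estimated correlation 0.504). The tables also argue against a single library (lowest median 0.36 over the fits without 1 library). A difference in RNA quality or cell content and an effect of the genotype stay open.

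The higher values of the elongating spermatid list are a second candidate for the length trend. The correction took the list's median from 0.10 (SD 0.25 over members) to 0.01 (SD 0.22) and its adjusted p by camera to 0.156. The call ended because the median fell and not because the spread grew. The uncorrected median lay above matched lists (at most 0.09 in the middle 95%), a range too narrow for genes that vary together. The trend and a change of these genes cannot be told apart. A larger share of elongating spermatids that raised all members alike would leave no spread beyond chance. Cochran's Q per degree of freedom was 6.59 on length-corrected values, where chance stays below 1.45 at the 95% point, so the members did not move alike. A share that raises members unequally, or beside changes of single genes, would also give a high Q. The test cannot exclude it, and a larger share stays open. The protamine genes Prm1 and Prm2, neighbours on chromosome 16, had corrected log2 fold changes of -0.51 and 0.38. An effect of the genotype on single genes of this list stays open, untested.

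Features at 0 in either genotype and at 20 or more counts in each library of the other numbered 8 among noncoding transcripts, against at most 2 in any other split of the libraries, and 1 among mRNA genes, against at most 2. The sum of H2ac18 and H2ac19 changed by -0.00025 on the log2 scale, but all of H2ac19 added to H2ac18 would move it by 0.07, less than 2 standard errors (0.12), so a division of counts between near-identical copies and a change of H2ac19 cannot be told apart. For the noncoding Chd5 transcript the sum of the features of that symbol changed by -0.27 ± 0.07 (edgeR, adjusted p = 0.110 over all genes). That is more than 2 standard errors from 0, where a plain loss of the transcript would give -0.39. If each read was counted once, counts divided among these features alone would leave the sum in place. The sum did not pass over all genes, and how shared reads were counted is not given, so it cannot decide. A division together with a change stays open. For the other transcripts counts divided among overlapping features and a change of the RNA cannot be told apart. Their sums could decide for 0 of the 3 with a coding gene of the same symbol, since AW554918 and Wdr48 are too small a part of their sums and the coding Pabpc1 gene itself rose. A sequence difference between the genotypes in these genes, and reads shared with features of other symbols, were not tested. Sums over the symbol for called transcripts not at 0 throughout a genotype changed by -0.25 ± 0.07 (SE) for Gtf2a1l and 0.53 ± 0.06 for Cep41 (edgeR, adjusted p = 0.145 and 0.0127). They changed by 0.34 ± 0.07 for Hnrnpu, -0.01 ± 0.05 for Atp5b and 0.03 ± 0.05 for Nr6a1.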
